A study of Homo sapiens with 38 samples.

How the data were processed

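The series holds 38 libraries in 17 groups from HEK293T cells, an established human embryonic kidney line, wild type or with the PUS10 gene knocked out. PUS10 is a pseudouridine synthase, an enzyme that turns uridine in RNA into pseudouridine. The groups were taken from the sample titles: polyA RNA and nuclear RNA (2 libraries per genotype each), small RNA treated with CMC or mock-treated with BEU (3 per genotype and treatment), ribosome footprints and their input RNA after MNase or RNase digestion (2 per genotype each), and PAR-CLIP of FLAG-tagged PUS10 (2 libraries). No label says that replicates were separate cultures, so the p-values of limma and camera measure only the spread between samples, and Fisher's exact test counts sites and measures no spread between samples.

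The submitters' processing notes name CASAVA, Trim Galore 0.3.3, TopHat2 2.1.0, Bowtie 1.2.2, HTSeq 0.9.1, Cufflinks 2.2.1 and the genome build hg19, without stating the order of the steps. The deposited MNase table gives RPKM for input and footprints in each of 8 libraries, per the file headers. Its translational efficiency is the ratio of footprint RPKM to input RPKM of the same replicate, per the file headers, and the deposited ratio matched that division within 1e-09 in every transcript. The same deposited table gives log2 changes between genotype means, and the p-value columns come from a test the authors did not name. The polyA table holds 1 value per genotype, which the authors combined over replicates; its unit was read as FPKM because the deposited values are decimals and the processing notes name Cufflinks, while the header names no unit. The nuclear table holds a mean signal per miRNA locus and genotype, averaged by the authors with a normalization that is not stated. Its 2 columns are headed WT and PT; PT was taken as the knockout because the labels name no other genotype, and the table does not list PUS10, so this reading has no check of its own. The tRNA tables give a score per site and replicate, headed stop difference by the authors; neither the formula nor the scale is given. All wild-type scores exceeded 5, so the deposited sites had been chosen on the wild-type libraries. The PAR-CLIP file lists site positions only.

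RPKM values of transcripts were summed by gene symbol, which turned 10799 transcripts into 6640 genes. Ratios of the RPKM values matched whole reads within a tolerance of 1e-11 in 100.0% of transcripts, which gave 7759455 to 13276228 reads behind each library; these recovered reads served depth and 1 alternative test. Input and footprint levels were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(RPKM + 1), for genes with a genotype mean of at least 1 RPKM. Efficiency was compared on log2 of the ratio, with the prior variance following the mean level of input and footprints. The plan named limma with trend on log2 efficiency and no other covariate. In that plain form the prior follows mean efficiency, which is given here as an alternative. Stop differences were compared with limma on the deposited score. The plan named limma on log2 or logit values, which cannot be taken of negative scores. Knockout scores ran down to -7.18, and the score was used as it stood. All p-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 counted as past the threshold. Gene lists were tested with camera at a preset correlation of 0.01 where at least 5 genes were measured, and again with an estimated correlation. The plan foresaw a test for polyA and nuclear RNA if values per replicate were given; with 1 value per genotype neither was tested. For polyA, log2 changes used a pseudocount of 1 FPKM for genes with at least 1 FPKM in a genotype, and each list's median was placed among 10000 random lists of the same size matched on mean expression, where a percentile under 2.5 or over 97.5 counted as apart. PAR-CLIP strand shares carry exact Clopper-Pearson intervals at 95% confidence, which cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

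The planned tests, the 25 gene lists, the rule for naming genes and the alternatives foreseen were fixed before the data were examined. The tests of efficiency and of stop differences then departed from the plan as given above. Not in the plan were the random lists for polyA RNA and the list tests of input RNA and footprints. The comparisons with coding length and between nuclear changes and overlapping genes were not in it either. The share of the same sign was planned for genes called in polyA RNA and was taken for those called in input RNA. The rule named PUS10 first; then, per tested comparison, the 10 genes per direction with the largest change among those past the threshold whose replicates did not overlap between genotypes and whose higher mean was at least 5; without a test, the 10 per direction with the largest change; up to 4 members per described list by smallest p; and the 10 largest losses and 5 largest gains among tRNA sites, here counted once per anticodon and position. For polyA the genes with values above 0 in both genotypes and at least 5 FPKM in a genotype were ranked as well. That choice was made after many of the largest changes proved to be genes listed at 0. Footprint and input genes were named by the rule for efficiency, and not every gene the rule picks is printed. Alternatives covered scaling, filters, pseudocounts, the replicate number as a block, leaving out each library, merged sites and 1 entry per anticodon; others were added after the data were seen, and the closing section says which.

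The scripts were tested on simulated data. For efficiency, input RNA and footprints, the simulated spread was a fixed value with counting noise, not the spread of these libraries. In the efficiency simulation over 6640 genes, 78% of genes changed by a log2 of 1 and 13% of those changed by 0.5 were recovered. For input RNA these shares were 100% and 37%, and for footprints 100% and 34%. In the simulation of 1481 tRNA sites, 67% of sites lowered by 10 and 27% of those lowered by 5 were recovered, with 5 false calls.

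Not analysed here were the 8 RNase libraries, which no deposited table covers, the classes and target genes of PAR-CLIP sites, which need an annotation of the build the files use, and values per replicate of polyA and nuclear RNA, which no table used here holds. The depth of the polyA, nuclear, small RNA and PAR-CLIP libraries is unknown from these files.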

Results

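The deposited tables covered PUS10 knockout and wild-type HEK293T cells by polyA RNA-seq, nuclear RNA-seq, CMC-based mapping of pseudouridine in tRNA, and MNase ribosome profiling with input RNA, together with PAR-CLIP sites of FLAG-tagged PUS10. Values per replicate were given for 3 small RNA comparisons per genotype and for 2 footprint and 2 input libraries per genotype. The MNase values rested on 11505810 and 13276228 reads in the wild-type input libraries, 11060589 and 8607389 in the knockout input, 8989013 and 8238652 in the wild-type footprints and 7759455 and 7898980 in the knockout footprints. PolyA and nuclear RNA had 1 value per genotype, so no difference between them has a replicate check.

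PUS10 itself stood at 3.37 FPKM in wild-type and 0.777 FPKM in knockout polyA RNA, which is 23.0% of the wild-type value; the gene is absent from the MNase table. The question here was which mRNAs differed without PUS10. The ranking of genes above 0 in both genotypes took only those with at least 5 FPKM in a genotype. Among genes above 0 in both genotypes, the neuronal scaffold gene JAKMIP2 was higher in knockout cells (0.0960 and 11.2 FPKM in wild type and knockout), as were DPYSL3 (1.28 and 15.98 FPKM), which acts in growing axons, the protease gene KLK8 (0.618 and 8.66), the secreted glycoprotein gene LGALS3BP (10.4 and 62.0), the growth factor gene PTN (0.148 and 5.23) and the matrix gene SPARC (1.59 and 12.3). SCARNA16, SEPP1, MID1 and KCNS3 followed with log2 changes of 2.01, 1.96, 1.81 and 1.78. Lower in knockout cells were BEX1 (5.48 and 0.0446 FPKM), TMEM183B (log2 change -1.67), the ketone body enzyme gene OXCT1 (-1.32), the stress-induced SESN2 (49.5 and 20.9 FPKM), DDAH1 (-1.20), SNORD10 (-1.18), the axonal motor gene KIF1A (-1.15), NAT8L (-1.09), ELOVL2 (-1.08) and SLC25A24 (-1.08). The largest changes of all belonged to small nucleolar RNAs listed at 0 in 1 genotype, such as SNORA61 (18196.2 FPKM in wild type, 0 in knockout), SNORA9 and SNORA16A (382 and 189 FPKM in wild type, 0 in knockout) and SNORA21, SNORA76 and SNORA70 (0 in wild type; 371, 371 and 330 FPKM in knockout). Such short RNAs are poorly captured by polyA selection, and no fold is given for those listed at 0. The same limit of capture holds for SCARNA16 and SNORD10 above. Of 12365 genes with at least 1 FPKM, 81 were higher and 30 lower by at least 2-fold, 21 of them listed at 0 in a genotype.

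Of the 23 gene lists with enough genes in the polyA table, 11 stood apart from random lists in these pooled polyA libraries. The interferon response list had a median log2 change of 0.51 over 14 genes, led by IFITM3 (3.84 and 13.5 FPKM in wild type and knockout), IFITM1 (4.24 and 12.3) and IFI6 (8.38 and 16.1), genes that type I interferon switches on. Hypoxia and glycolysis genes (median 0.24 over 23) included ALDOC (6.40 and 13.05 FPKM) and NDRG1 (25.5 and 48.4), and heat shock genes had a median of 0.23 with HSPB1 at 64.0 and 96.5 FPKM. Targets of the stress factor ATF4 had a median of -0.31 over 23 genes, with CTH at 14.8 and 7.02 FPKM, CHAC1 at 8.81 and 4.86 and SLC7A11 at 12.1 and 6.89. Histone genes (median -0.21, HIST1H4H at 3.34 and 1.23 FPKM), HOX genes (-0.14), cell cycle genes (-0.12) and tRNA synthetases (-0.10) had medians below 0 too, with members on both sides. Above 0 were 4 of 22 histone genes, 4 of 28 HOX genes, 6 of 30 cell cycle genes and 7 of 20 synthetases. The histone genes with the largest changes, HIST1H2AI, HIST1H4E, HIST1H4H and HIST1H2BL, had at most 5.13 FPKM in either genotype. At such levels the pseudocount weighs on the change. HIST1H3C and HIST1H2BI were at 0 in both genotypes, though both were measured in the MNase input RNA. The polyA median of this list is therefore a poor guide to the level of histone RNA. RRM2 had 124 and 67.0 FPKM and CCNA2 102 and 128 among cell cycle genes, while YARS had 165 and 80.7 FPKM and HARS 60.1 and 86.6 among synthetases. Ribosomal protein, cholesterol synthesis and fibroblast or epithelial marker lists had medians of 0.04, 0.13 and 0.20. Percentiles lay at 0.13 or below for the 5 lower lists and at 98.0 or above for the 6 higher ones, as a description of these libraries and not of the genotypes.

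Nuclear RNA was deposited as signal at miRNA loci. Such signal can come from primary miRNA transcripts, the precursors that Drosha cleaves. Other nuclear RNA covering a locus cannot be told apart from them here. The knockout values had a median log2 change of 0.19 over 661 loci, and changes below are relative to that shift. The loci of mir-6720 (signal 215 in wild type and 1358.0 in knockout, log2 change 2.47) and mir-4469 (103.0 and 534, log2 change 2.18) stood highest. PolyA RNA of the genes they overlap, FOXF2 and RNF170, changed by 0.03 and 0.13. Overlap was taken by position without regard to strand, so these genes need not be the transcripts that carry the miRNAs. Next came mir-6880 (0.83), mir-4489 (0.83), mir-4688 (0.78), mir-6787 (0.77) and mir-196a-1 (0.74). At the low end were mir-374b (115 and 64.0; -1.03), mir-5685 (111 and 61.9; -1.01), the HOX-linked mir-10a (251 and 152; -0.91), mir-3671 (-0.86), mir-186 (386 and 251; -0.81) and mir-101-1 (-0.78). Of 6 let-7 loci, whose miRNAs repress growth genes, let-7g was lowest (125 and 83.4; -0.77) and let-7f-1 was higher (0.21), while let-7d was at 0.18 before the shift was taken out and -0.00 after it. In the mir-17-92 cluster, mir-17 had 694 and 779 (-0.02) and mir-92a-1 had 269 and 237 (-0.37). Changes of at least 1.5-fold numbered 46 higher and 10 lower as deposited, but 16 higher and 26 lower after median scaling. Across 407 loci inside genes with a polyA value, the nuclear change and that of the overlapping gene had r 0.257 and rho 0.246. Strand was not considered there either, and loci are not independent replicates. A total of 47.7% of the wild-type signal lay in mir-3687, mir-6077-2, mir-6077-1 and mir-3648.

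The tRNA tables asked which pseudouridine sites depend on PUS10, whose reported targets lie in the T loop, near positions 54 and 55. The largest fall was in tRNA-Trp-CCA at file position 53, from a stop difference of 44.6 ± 7.61 (SD, n = 3) in wild type to 9.79 ± 1.98 in knockout (limma adjusted p 0.00562). In tRNA-Ala-AGC, position 55 fell from 22.6 ± 5.80 to 0.0347 ± 1.23 (n = 3 per genotype, limma adjusted p 0.00938), while its position 54 had 29.0 and 34.7 (limma adjusted p 0.521). tRNA-Arg-ACG position 54 fell from 29.8 ± 6.50 to 10.5 ± 2.09, tRNA-Val-AAC position 55 from 22.6 ± 3.64 to 4.87 ± 0.978, and tRNA-Val-CAC positions 55 and 56 from 22.2 ± 3.58 and 23.1 ± 3.65 to 4.80 ± 0.963 and 4.97 ± 0.997 (SD, n = 3). The glutamine tRNAs fell at position 53, Gln-CTG from 21.8 ± 4.59 to 7.57 ± 1.63 and Gln-TTG from 16.995 ± 4.40 to 2.91 ± 0.829. These 8 anticodon positions passed among 269, and each had all 3 knockout libraries below all 3 wild-type libraries. The Val-CAC positions need not be separate nucleotides of 1 tRNA. Position 55 had 7 gene copies and position 56 had 1, with close values in each library. Thr-TGT position 53 had 31.8 and 19.96 and was not past the threshold, nor was Arg-TCT position 52, where knockout replicate 2 stood at -3.95 and the other knockout libraries at 30.5 and 29.1. The 5 largest gains, Pro-AGG at positions 77, 61 and 54 and Pro-CGG and Pro-TGG at 54, lay between 10.7 and 11.8 and were not past the threshold (adjusted p 0.212 to 0.216 by limma). They need not be separate signals. Pro-AGG had wild-type values of 30.87, 20.09 and 27.87 at position 77 and 30.87, 20.11 and 27.93 at 61, and the values at 54 were close among the proline tRNAs.

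**Figure D1:**
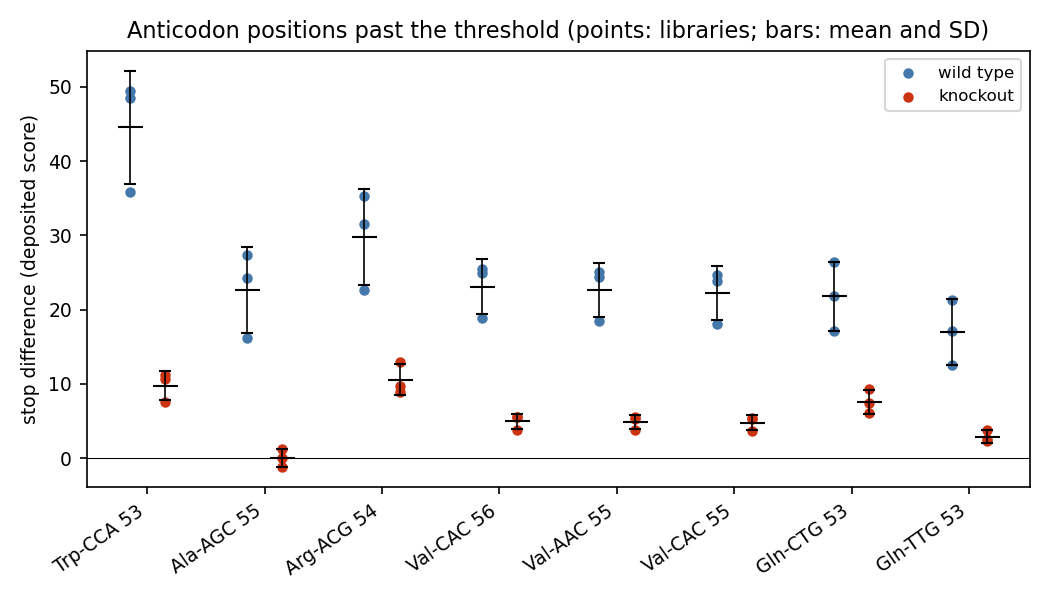
Stop difference, as the deposited score, of the 8 anticodon positions past the threshold, with points for the 3 libraries of each genotype and bars for mean and SD. The knockout libraries lay below the wild-type libraries at each, with knockout means between 0.0347 and 10.5.

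Counted per gene copy, 60 of 1481 sites fell and 0 rose by limma, with 178 sites at an unadjusted p under 0.05. All 60 lay at file positions 51 to 60, which hold 454 sites, and none of the 519 sites at positions 1 to 30, the 404 at 31 to 50 or the 104 above 60 passed. They comprised 15 of 15 copies of Ala-AGC, 7 of 7 of Trp-CCA, 7 of 7 of Arg-ACG, 8 of 8 of Val-AAC, 7 of 7 and 1 of 1 of Val-CAC, 9 of 10 of Gln-CTG, 5 of 5 of Gln-TTG and 1 of 5 of Val-TAC, where 1 copy fell from 61.7 to 29.7. All 60 had non-overlapping genotypes, but they were picked by a test on the same columns, so this adds no support. Over all sites the share was 23.1%, against 10% by chance for 3 against 3. Centred on each library's median, 153 sites fell and 28 rose. The count was 0 without wild-type replicate 3 and 0 without knockout replicate 1 (257 and 167 sites at an unadjusted p under 0.05), 114 without wild-type replicate 2, and 34 without knockout replicate 2 or 3. Copies of a tRNA share reads, and the 1481 sites held 1028 distinct sets of values.

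**Figure D2:**
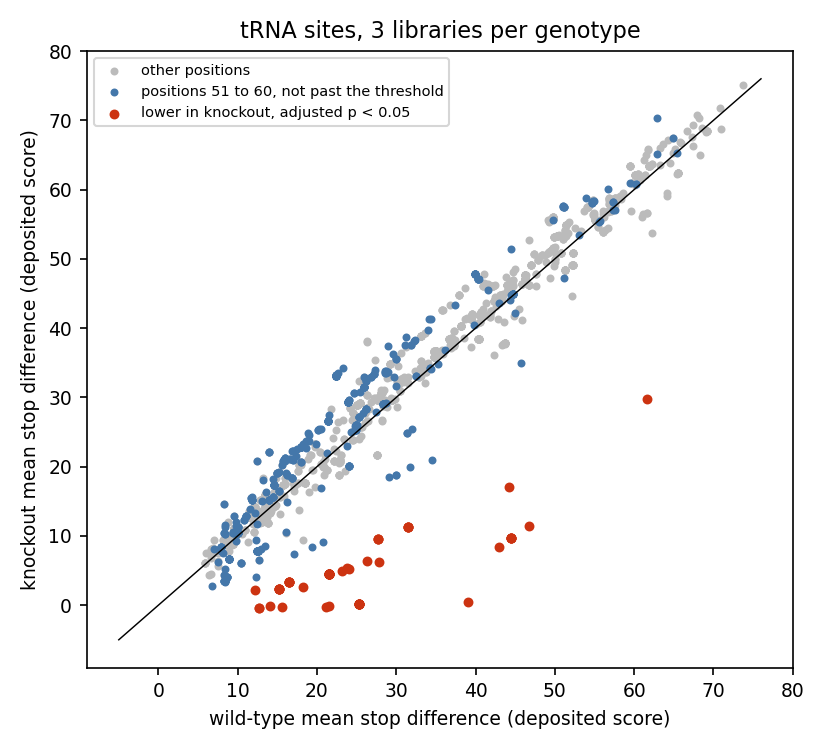
Knockout against wild-type mean stop difference, as the deposited score, for 1481 tRNA sites with 3 libraries per genotype; the line marks equal values. The 60 sites that fell lie below it, and all have file positions 51 to 60.

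Neighbouring file positions 54 and 55 were then compared. At position 55, all 15 alanine sites and 16 of 20 valine sites fell, while tyrosine (34.97 and 38.7 in wild type and knockout), lysine (14.6 and 19.1) and phenylalanine (29.4 and 30.01) had none that passed. At position 54, 7 of 18 arginine sites fell (20.2 and 10.05 over all 18), and none passed among 25 cysteine (28.8 and 29.8), 20 proline (22.5 and 33.2) or 10 histidine sites (44.7 and 44.9). In all, 7 of 163 sites fell at position 54 and 31 of 120 at position 55 (Fisher's exact test, two-sided, p 2.1e-07 over gene copies). Counted once per anticodon, 1 of 25 and 3 of 19 fell (Fisher's exact test, p 0.3002). With identical value sets counted once, an alternative chosen after seeing the data, 2 of 123 and 14 of 71 fell (Fisher's exact test, p 1.9e-05). File positions run up to 90 and were not converted to the standard tRNA numbering, so a file position need not be the same nucleotide in every tRNA.

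Input RNA of the MNase libraries gave the mRNA changes with replicates. ZCCHC12 rose from 45.4 ± 2.92 to 107 ± 11.3 RPKM (SD, n = 2; limma log2 change 1.21, adjusted p 0.00134) and the syndecan gene SDC2 from 53.7 ± 1.26 to 119 ± 2.11. The protocadherin gene PCDH9, LGALS3BP, the giant cadherin gene FAT3, ARRDC4, SAR1B, C4orf3 and IFI30 rose by log2 0.99, 0.97, 0.95, 0.93, 0.92, 0.85 and 0.82. The nucleolin gene NCL fell from 170 ± 33.9 to 72.5 ± 0.109 RPKM (log2 -1.20), the DNA repair gene PARP1 from 357 ± 29.8 to 159 ± 14.9 (-1.16), the replication helicase gene MCM2 from 109 ± 3.96 to 48.4 ± 12.5 (-1.17) and the intermediate filament gene VIM from 334 ± 19.04 to 152 ± 1.64 (-1.13). The chromatin factor gene SUPT16H, SESN2, MSN, DDB1 and TLN1 changed by -1.20, -1.17, -1.05, -1.04 and -1.02. By limma 272 genes rose and 291 fell of 6640. Without wild-type replicate 1 the count was 185, without knockout replicate 1 it was 1726 and without knockout replicate 2 it was 997.

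In the input RNA, 6 lists passed with camera at the preset correlation and none with an estimated one. Histone genes had a median log2 change of -0.48, with 1 of 33 above 0 and HIST1H4A at -0.83 ± 0.11 (SE); 19 fell over all genes and 29 adjusted over the list alone (adjusted p = 0.474 with an estimated correlation). Heat shock genes had a median of -0.33, led by HSPA1B (-0.97) and HSPA1A (-1.02), a near-identical pair that can share reads, and HSP90AB1 (-0.64); 5 fell over all genes and 7 adjusted over the list alone (adjusted p = 0.316 with an estimated correlation). Cell cycle genes had a median of -0.24 with MCM2, RRM2 (-0.70), RRM1 (-0.76) and MCM4 (-0.62); 7 fell and 1 rose over all genes, 12 and 1 adjusted over the list alone (adjusted p = 0.316 with an estimated correlation). ATF4 targets had a median of -0.24 with SESN2, PHGDH (-0.84) and PCK2 (-0.59); 3 fell over all genes and 5 adjusted over the list alone (adjusted p = 0.474 with an estimated correlation). tRNA synthetases had a median of -0.21 with YARS (-0.79), AARS (-0.63) and EPRS (-0.45); 3 fell over all genes and 7 adjusted over the list alone (adjusted p = 0.316 with an estimated correlation). Of 7 neuronal genes (median -0.37), NEFM (-0.91) and INA (-0.71) fell over all genes, and 5 fell and 2 rose adjusted over the list alone (adjusted p = 0.474 with an estimated correlation).

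PolyA RNA and MNase input RNA come from separate libraries of the same genotypes. ZCCHC12 and SDC2 were higher in knockout polyA RNA as well (log2 1.33 and 0.91), and SESN2 and VIM were lower (-1.21 and -0.71). NCL, PARP1, MCM2, SUPT16H, DDB1, TLN1 and MSN had polyA changes of only -0.23, -0.10, -0.05, -0.28, -0.12, -0.11 and -0.20. HSPA1B, whose polyA change was 0.29, fell in input RNA. Over 6178 genes the changes had r 0.530 and rho 0.475, a correlation across genes, which are not independent replicates. Of 525 genes past the threshold in input RNA, 468 (89.1%) had the same sign in polyA RNA. Genes that rose in input had medians of 0.51 in input and 0.24 in polyA RNA, and genes that fell had -0.57 and -0.23.

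**Figure D3:**
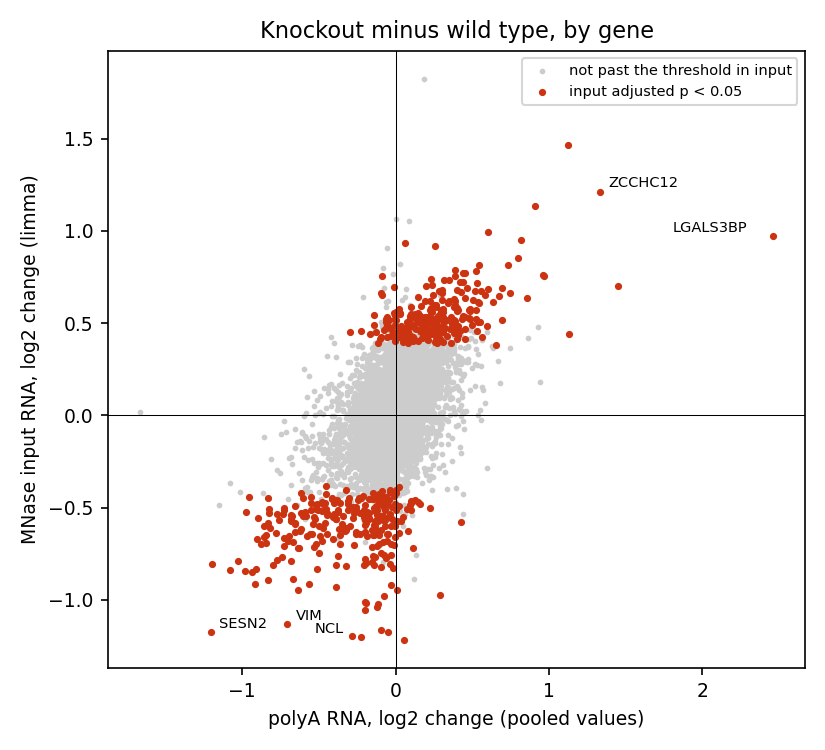
Log2 change of MNase input RNA (limma, 2 libraries per genotype) against that of polyA RNA (pooled values) for 6178 genes, with genes past the threshold in input RNA in red. NCL lies at -0.23 on the polyA axis and at -1.20 in input RNA.

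Footprints count the RNA fragments that ribosomes covered, so their level rises with the RNA of a gene and with the ribosomes on it. LGALS3BP footprints rose from 36.8 ± 1.94 to 129 ± 0.533 RPKM (SD, n = 2; limma log2 change 1.78, adjusted p 1.6e-06) and ZCCHC12 from 39.4 ± 1.17 to 117 ± 3.68. FAT3, AHNAK, REEP6, NDNF, MRC2, the NADPH oxidase subunit gene CYBA and the respiratory chain gene NDUFB2 rose by 1.59, 1.18, 1.17, 1.17, 1.12, 1.09 and 1.08. SUPT16H fell from 136 ± 6.33 to 31.4 ± 1.54 RPKM (log2 -2.08), the talin gene TLN1 from 41.4 ± 0.290 to 10.8 ± 0.362 (-1.84), the DNA methyltransferase gene DNMT1 from 62.8 ± 0.451 to 18.5 ± 0.806 (-1.71) and NCL from 736 ± 6.64 to 235 ± 4.57 (-1.64). SUPT6H, CKAP5, the initiation factor gene EIF5B, the helicase gene DHX9, MSN and TOP1 changed by -1.75, -1.69, -1.66, -1.59, -1.51 and -1.50. By limma 1896 genes rose and 1322 fell. With median-of-ratios size factors 1671 rose and 1531 fell, and with the coding length trend removed, an alternative chosen after seeing the data, 1279 rose and 1403 fell.

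Among lists in the footprints, 8 passed with camera at the preset correlation. Ribosomal protein genes had a median of 0.19 with RPS14 (0.87), RPL34 (0.73) and RPL27 (0.47); 51 rose and 10 fell over all genes, 54 and 10 adjusted over the list alone (adjusted p = 0.305 with an estimated correlation). With the coding length trend removed, an alternative chosen after seeing the data, the ribosomal protein list passed in the opposite direction, with a median of -0.09 (camera adjusted p 4.7e-05 at the preset correlation). Cell cycle genes had a median of -0.27 with MCM2 (-1.35), TOP2A (-1.22) and RRM1 (-1.10); 20 fell and 2 rose, as they did adjusted over the list alone (adjusted p = 0.305 with an estimated correlation). Heat shock genes (median -0.43, HSP90AB1 -0.77, HSPH1 -1.03), tRNA synthetases (-0.24, YARS -0.95) and translation factors (-0.06, EIF3C -1.15, EIF4G1 -1.03) had 9, 13 and 14 that fell and 2, 1 and 8 that rose over all genes. Adjusted over the list alone, 10, 13 and 15 fell and 2, 1 and 9 rose (adjusted p = 0.352 with an estimated correlation for each). Endoplasmic reticulum stress genes (0.28, CANX 0.35) and matrix and adhesion genes (0.44, COL6A1 0.83, against VIM at -0.88) had 11 and 9 that rose and 2 and 1 that fell, both over all genes and adjusted over the list alone (adjusted p = 0.352 with an estimated correlation for both). ATF4 targets had a median of -0.19 with SESN2 (-1.03) and ASNS (-0.81); 8 fell and 2 rose over all genes, 8 and 3 adjusted over the list alone (adjusted p = 0.371 with an estimated correlation).

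Translational efficiency set footprints against input RNA. EIF5B, which joins the ribosomal subunits at initiation, fell from an efficiency of 0.494 ± 0.0287 to 0.157 ± 0.0148 (SD, n = 2; limma log2 change -1.66, adjusted p 0.00231), with input RNA at -0.09 and polyA RNA at -0.09. The ribosome biogenesis gene UTP20 (-1.25), SUPT6H (-1.23), DNMT1 (-1.11), the microtubule gene CKAP5 (-1.03), PRPF4B (-0.998), CHD4 (-0.93), DHX57 (-0.92), DHX9 (-0.91) and the repair gene XPC (-0.90) fell as well. The cell cycle factor gene E2F1 rose from 0.237 ± 0.108 to 0.641 ± 0.182 (log2 1.48, limma adjusted p 0.0460), with input RNA at -0.89 and footprints at 0.58. YIF1B (1.37), MRC2 (1.11), FAT3 (0.99), KCTD12 (0.98) and HLA-F (0.95) rose, as did the histone genes HIST1H4I (1.08), HIST1H2BI (1.01), HIST2H2BE (0.97) and HIST1H3D (0.95). By limma 60 genes rose and 32 fell, with 1388 at an unadjusted p under 0.05; centred on the median of each library, 98 rose and 29 fell. With the prior following mean efficiency, the plain form of the planned test, 22 rose and 33 fell. Other alternatives were chosen after seeing the data. With limma-voom on recovered reads, 87 rose and 110 fell. With the coding length trend removed, 0 rose and 1 fell (1188 at an unadjusted p under 0.05). Without wild-type replicate 1 or wild-type replicate 2 the count was 0 (864 and 781 genes at an unadjusted p under 0.05), EIF5B included (limma adjusted p 0.0721 and 0.0639), and without knockout replicate 1 it was 989. In the authors' deposited table, 226 transcripts were higher and 325 lower in efficiency at a p-value under 0.05.

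Histone genes had a median efficiency change of 0.57, with all 33 above 0. With the coding length trend removed, an alternative chosen after seeing the data, their median was 0.34, as was that of matrix and adhesion genes, which stood at 0.25 before and had not passed (camera adjusted p 0.0737 before and 8.8e-05 after at the preset correlation; 0.677 with an estimated correlation before, which was not run after). HIST1H3C (0.94 ± 0.13, SE), HIST1H3D (0.95 ± 0.15), HIST1H3H (0.76 ± 0.12) and HIST2H3D (0.91 ± 0.16) had the smallest p; 10 rose over all genes and 31 adjusted over the list alone (adjusted p = 0.677 with an estimated correlation). Their input RNA had a median of -0.48, while their footprints had a median of 0.07, with 14 that rose and 5 that fell over all genes and, with that trend removed, a median of -0.25 (camera adjusted p 1.03e-07 at the preset correlation). HIST1H3D was at 0.47 in footprints and -0.48 in input RNA. Near-identical histone copies share reads. Hypoxia and glycolysis genes had a median of 0.26 with GAPDH at 0.36, ENO1 at 0.29 and PGAM1 at 0.27, and 13 of 13 were above 0; none passed over all genes or adjusted over the list alone by limma (camera adjusted p 0.00956; adjusted p = 0.677 with an estimated correlation). Ribosomal protein genes had a median of 0.13 with RPS26 at 0.43 and RPS14 at 0.45, and 55 of 71 were above 0; none passed over all genes or adjusted over the list alone by limma (camera adjusted p 0.00294; adjusted p = 0.677 with an estimated correlation). With the coding length trend removed, hypoxia and glycolysis genes still passed at the preset correlation (median 0.16, camera adjusted p 0.0352), while ribosomal proteins did not (median -0.08, camera adjusted p 0.512). Pseudouridine synthases (median 0.13, RPUSD4 0.66) and miRNA machinery genes (-0.19, TARBP2 0.60) had none past the threshold over all genes and 1 each adjusted over the list alone.

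Genes with short coding sequences gained footprints relative to long ones. With genes put into 5 equal groups by coding length, the median footprint change was 0.27 in the 1328 genes of the shortest group and -0.14 in those of the longest. Efficiency had medians of 0.17 and -0.16 in these groups, and input RNA 0.10 and -0.01. Genes whose efficiency rose had a median coding length of 509 nt and those whose efficiency fell 3442 nt, against 1461 nt for all 6640 genes. Across genes, coding length had rho -0.47 with the footprint change, -0.42 with that of efficiency and -0.17 with that of input RNA; genes are not independent replicates. Over the 4 pairs of a knockout and a wild-type library, rho ran from -0.46 to -0.44 for footprints, from -0.50 to -0.27 for efficiency and from -0.31 to -0.01 for input RNA. Between the wild-type replicates it was 0.02, -0.29 and 0.41.

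**Figure D4:**
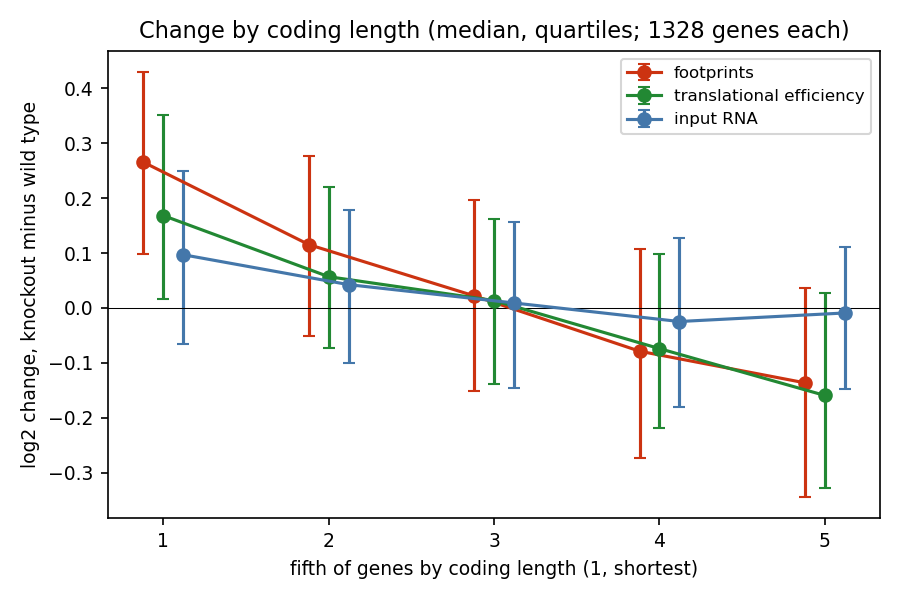
Median log2 change with quartiles in 5 groups by coding length (1328 genes each) for footprints, translational efficiency and input RNA, knockout minus wild type. The footprint median went from 0.27 in the shortest group to -0.14 in the longest.

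PAR-CLIP listed where FLAG-PUS10 crosslinked to RNA, as 2689 sites on hg19 with a median width of 36 nt (1 to 271). On the autosomes, the densest stretches were chromosome 6 from 28000001 to 29000000 with 45 sites, 27000001 to 28000000 with 35 and 26000001 to 27000000 with 34, a region known for its clusters of tRNA and histone genes. Chromosome 2 from 61000001 to 62000000 held 27 sites, chromosome 16 from 2000001 to 3000000 held 26 and chromosome 5 from 180000001 to 181000000 held 26, against a median of 2.0 over the 909 autosomal windows of 1 Mb with a site. Stretches on other chromosomes are not listed. The plus strand held 1237 of the 2542 autosomal sites, or 48.7% (95% Clopper-Pearson interval 46.7 to 50.6). The file gives no score, read count or control, and sites were not assigned to genes.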

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

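Chosen after seeing the data were the alternatives that used recovered reads, removed the coding length trend, took transcripts singly or centred the tRNA sites. So were those that counted identical value sets once or left out polyA genes listed at 0. The list alternatives for polyA RNA, input RNA and footprints were chosen then too. Letting the prior follow mean efficiency is the plain form of the planned test. The count of efficiency changes, 92 genes, was 197 with limma-voom on recovered reads, 55 with the prior following mean efficiency and 1 with the coding length trend removed. The gene left was EIF5B, at a log2 change of -1.51 against -1.66; the removal takes out by construction whatever follows length, and why each other call ended was not tested. Leaving out 1 library gave 0 to 989 genes for efficiency and 185 to 1726 for input RNA. Efficiency had 0 without wild-type replicate 1 or 2, where limma had 864 and 781 at an unadjusted p under 0.05; the lone sample left is assumed to vary like the other group. Taking transcripts singly gave 889 calls for input RNA against 563 and 4890 for footprints against 3218, from more entries tested. Scaling, filters and pseudocounts kept these counts within 1.5 times. With an estimated correlation, 0 lists passed in efficiency, input RNA or footprints, against 3, 6 and 8.

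With the replicate number as a block, 287 genes were called for efficiency, 881 for input RNA and 3374 for footprints, and 3, 6 and 6 lists. For tRNA sites the block left 42 falls of 60. The values gave no sign that the numbers pair the samples across genotypes, which does not show that they were unpaired. Replicate differences of the genotypes had correlations of -0.03, -0.04 and 0.02, and same-numbered site columns -0.09, -0.48 and -0.25. No paired analysis was possible for polyA and nuclear RNA, which have 1 value per genotype.

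For tRNA sites, 60 falls became 39 with sites within 1 nt merged, 8 once per anticodon and position, 25 with identical value sets counted once and 153 (with 28 rises) when centred; leaving out 1 library gave 0 to 114. The difference between positions 54 and 55 had p 0.3002 by Fisher's exact test once per anticodon and 1.9e-05 with identical value sets counted once. Arg-TCT position 52 had a difference of -10.5 and, leaving out 1 library, -16.5 to 0.738, the last without knockout replicate 2, because that library alone was low. For other lost calls the cause was not tested. In polyA RNA, 111 genes at 2-fold became 56 with at least 5 FPKM and 268 with a pseudocount of 0.1.

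Of 24 named efficiency genes past the threshold, 24 lost it under some alternative, as did 18 of 57 for input RNA, 0 of 20 for footprints and 8 of 8 site positions. None of these changed sign, and where a call was lost the change was at least 63.9% of its reported size for efficiency, 56.4% for input RNA and 85.8% for sites. Simulations recovered 13% of changes of a log2 of 0.5 in efficiency. Their fixed spread was not taken from these libraries. Not run were the alternatives foreseen for PAR-CLIP classes and targets, the list tests in polyA RNA and leaving out polyA or nuclear replicates, since the files hold no scores, classes or values per replicate.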

Other observations

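The tests of explanations in this part were all chosen after the results were seen. Of 19 miRNA machinery genes, 2 rose and 8 fell in the footprints (median -0.14), and the list did not pass (camera adjusted p 0.0566). The RNA helicase gene DDX5, which assists Drosha, was at -0.96 and the Dicer partner gene TARBP2 at 0.69. Of the let-7 targets, 7 of 21 were above 0 in polyA RNA (median -0.08) and 3 of 14 in footprints (median -0.09, with 2 that rose and 4 that fell); neither passed (percentile 3.82 among random lists and camera adjusted p 0.265). Among those above 0, the D cyclin gene CCND1 had 3.34 and 8.51 FPKM in wild-type and knockout polyA RNA, 0.44 in input RNA and 0.63 in footprints.

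Stop differences fell only at file positions 51 to 60 among the 60 calls. For near-identical tRNA copies sharing reads, the prediction was a single isotype when each anticodon and position counts once. A total of 5 isotypes kept a call, so the falls were not confined to copies of 1 tRNA. How far shared reads raised the 60 calls cannot be told from this, since copies can share reads within every isotype. Sites chosen on wild-type values would fall elsewhere too, yet the 876 sites outside these positions with wild-type means in the same range (12.2 to 61.7) had a median difference of 1.45 and a lowest value of -8.92, against a median of -18.1 for the called sites. Loss of PUS10, the difference the design names, stays open and was not tested apart from these values. Of the 10 splits of the 6 columns, 1 gave as many calls, the real one with 60 against at most 0 in the others, and 10 splits are too few for a share under 0.05.

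Footprint changes went down with coding length. Length bias that varies from library to library would show between replicates, where rho was at most 0.0258 in size for footprints; in input RNA and efficiency the wild-type replicates differed with rho 0.41 and -0.29, so the efficiency trend may hold a part of that kind. The trend was also present among the 6536 genes outside the histone and ribosomal protein lists, where rho was -0.474. Those lists are so small a share of all genes that leaving them out could hardly have moved rho. A preparation shared by both knockout libraries cannot be told apart from the genotype, as each of the 4 pairs of a knockout and a wild-type library had the trend, the weakest at -0.443.

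Of 266 genes that fell in input RNA and had a polyA value, 135 had a polyA change above -0.25; in footprints, which had no part in choosing them, 122 fell. Selection of the lowest input values would bring picked genes back toward 0 in libraries not used for picking, and they went part of the way: genes picked in the first pair of libraries had a median of -0.65 there and -0.39 in the second, and genes picked in the second had -0.65 there and -0.348 in the first. As the whole cause it would bring them back to the medians of all genes above that polyA bound, 0.05 and 0.04 in the first and second pair. Noise in the single pooled polyA value stays open and was not tested. With the coding length trend removed, 97.0% of these genes kept their call, but that share decides little. In input RNA the median change was 0.10 in the shortest length group and -0.01 in the longest, while these genes had a median of -0.56. Removing so small a trend could hardly have ended their calls. Other cultures or preparations behind the polyA libraries cannot be told apart from a difference between the RNA kinds, with r 0.530 across genes lying between the bounds set for either; no biological explanation was tested.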
